A study of Homo sapiens with 13 samples.

How the data were processed

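Anti-GFP ChIP-seq was performed in MV4-11 cells after crosslinking with disuccinimidyl glutarate and formaldehyde, per the labels' protocols. The labels list 13 samples: 10 GFP-DNMT1 libraries, 1 parental library and 2 inputs. No file of the inputs was used here. Groups and replicate numbers were taken from the sample labels. The series' design text and the sample labels number the batches in opposite ways, and the sample labels were followed (WT, RFTSdel and parental in batch 1, NTC and UHRF1KO in batch 2).

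Each of the 11 deposited files is a list of broad peaks called separately in 1 library, not on pooled replicates. Per the submitters' processing notes, cutadapt, BWA, Picard, MACS2 and deepTools were used with the GRCh38 build. Their versions and settings, and the control library for peak calling, are not given in the sources used here. The deposited fold column is the ratio of signal to background that the authors' caller gave for a peak. The deposited −log10 columns are −log10 p and −log10 q from the authors' caller. The deposited score column equalled 10 times −log10 q rounded down in 99.995% of peaks. The lowest −log10 q was just above 1 in each list, so a cutoff of q 0.1 is implied by the values. The lists hold no read counts: depth is unknown, a longer list can come from deeper sequencing or stronger enrichment, and the Wilson intervals (95%) cover counting error only.

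Peaks on chromosomes 1 to 22, X and Y were kept, and peaks that overlapped a parental peak by 1 bp were removed. This left between 4254 and 32534 peaks per GFP-DNMT1 library. A peak was shared when it overlapped a peak of the other list by at least 1 bp. Random placement moved the peaks of a list within their chromosomes 200 times. All 10 lists were merged into 48783 regions, and a region was called in a library when a peak of that library lay in it. "Lost" and "gained" regions are those called under DMSO only or under DNMT1i only.

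Gene positions came from RefSeq for GRCh38.p14 (59679 genes, 20037 protein-coding), without strand, exons or sequence. The planned promoter share was therefore taken as the share within 1 kb of either end of a protein-coding gene, exon or intron positions are not given, and the planned GC and CpG comparison was not run. Random gene lists (10000) were matched on deciles of gene length in place of promoter CpG content. Chromosome ends for random placement were the largest coordinate of a gene or peak. Merging used a sweep in Python in place of bedtools.

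The 5 DMSO and DNMT1i pairs were tested with an exact two-sided sign-flip permutation test, which cannot go below 0.063. RFTSdel libraries were paired by replicate number. Comparisons of UHRF1KO with NTC and of RFTSdel with WT had 1 library in at least 1 group and were not tested. The 11 gene lists (DNA methylation and SUMO, viral sensing and interferon, germline and cancer-testis, imprinted, myeloid and leukaemia, lymphoid and erythroid, zinc finger, clustered protocadherin, olfactory receptor, replication-dependent histone, ribosomal and housekeeping) and all tests named as planned were fixed before the data were examined, and list p-values were adjusted by Benjamini-Hochberg. Named peaks are, per contrast and direction, the 5 with the highest −log10 q and no overlap in the other list (in RFTSdel, called in both replicates, absent from both of the other group, and ranked by the lower −log10 q of the 2 replicates, with the values printed taken from replicate 1). Other named sites are the 5 strongest parental peaks, the 10 longest regions lost in all 5 pairs, the 10 best ranked regions called in all 10 libraries, up to 4 list members marked in the most libraries, and DNMT1 and UHRF1. A housekeeping list member that this rule selects is not reported here. Members of the lists named in the account of the wild-type pairs were chosen after their values were seen.

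Alternatives kept the parental peaks, required −log10 q of at least 2 or 4 or a fold enrichment of at least 4, merged peaks within 5 kb, used all contigs, required 50% of a peak to be covered, cut lists to equal length, used a 3 kb window, gene bodies or gaps between protein-coding genes, took NTC as comparator for RFTSdel, and left out each replicate. The overlap, merging and list code was tested on simulated lists built from the 23568 NTC DMSO peaks and returned 10 of 10 known answers. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.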

Results

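Chromatin bound by GFP-tagged DNMT1, the methyltransferase that copies CpG methylation onto newly replicated DNA, was profiled by anti-GFP ChIP-seq in MV4-11, a human acute myeloid leukaemia cell line. By the sample labels, the cells overexpressed GFP-DNMT1 and carried a guide against DNMT1, and the lists give no check that the endogenous enzyme was lost. The tagged protein was either wild type or lacked the RFTS domain, the targeting domain near its N-terminus (RFTSdel). A second series carried wild-type GFP-DNMT1 with a non-targeting guide (NTC) or a guide against UHRF1 (UHRF1KO). UHRF1 recognises hemimethylated DNA and recruits DNMT1 to it. Each line received DMSO or a DNMT1 inhibitor (DNMT1i, 100 nM) for 7 days. Peak lists of 11 libraries were compared. NTC, UHRF1KO and WT had 1 library per treatment, RFTSdel had 2 per treatment, and parental cells without GFP had 1. The lists hold no read counts, so sequencing depth is unknown, and differences between single libraries had no replicate check. Nothing in the labels says that the RFTSdel replicates came from separate cultures, so their spread may be technical. The lists contain no expression values and gave no check of the UHRF1 knockout itself.

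The parental library gave the background of the antibody. Its 426 peaks lay mostly at gene ends: 84.3% (95% Wilson interval 80.5 to 87.4) came within 1 kb of an end of a protein-coding gene, against 4.10% for randomly placed peaks. The 5 strongest by the authors' −log10 q overlapped CHMP6 on chromosome 17 (80991606 to 80992170, GRCh38), CLPTM1 on chromosome 19, SCRIB on chromosome 8, GET4 on chromosome 7, and the LYSMD1 and SCNM1 genes on chromosome 1. Of the 10 GFP-DNMT1 libraries, 9 called between 70.4% and 99.3% of the parental peaks, and WT DNMT1i called 16% (68 of 426, interval 12.8 to 19.7). Peaks overlapping a parental peak were removed before the comparisons. All fold enrichments and q values given for single peaks are the authors' and were used only to rank, filter or describe peaks within a list.

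DNMT1 occupancy under the inhibitor was addressed by the 5 matched DMSO and DNMT1i pairs. Fewer peaks were called after DNMT1i in 5 of 5 pairs. The number was 23568 under DMSO and 5844 under DNMT1i in NTC, 32534 and 4642 in UHRF1KO, and 16709 and 4254 in WT. In RFTSdel it was 12245 and 7561 in replicate 1 and 14026 and 11141 in replicate 2. The mean log2 ratio was −1.56 ± 1.02 (SD, n = 5 pairs; exact two-sided sign-flip permutation test, p = 0.063, the smallest this design allows). Covered length gave −1.57 ± 1.00 (n = 5, exact p = 0.063). By the batch in the sample labels, the mean log2 ratio of peak number was −1.0 ± 0.86 in batch 1 (WT and both RFTSdel pairs, n = 3) and −2.41 ± 0.56 in batch 2 (NTC and UHRF1KO, n = 2). The 2 wild-type lines had similar ratios, −1.97 for WT in batch 1 and −2.01 for NTC in batch 2, and the mean of batch 1 includes the RFTSdel pairs (−0.70 and −0.33).

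**Figure D1:**
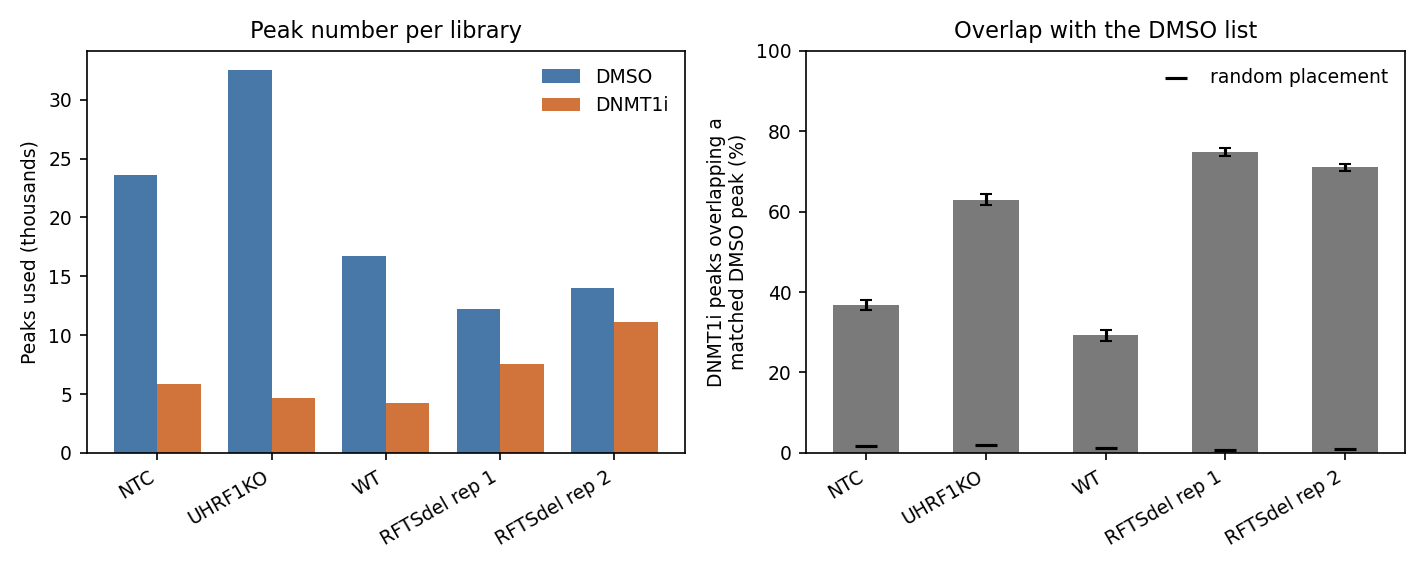
Left, peaks used per library (in units of 1000) under DMSO and DNMT1i for the 5 pairs. Right, share of DNMT1i peaks (%) overlapping a matched DMSO peak, with 95% Wilson intervals as error bars and the mean of 200 random placements as dashes; the NTC and WT shares were 36.7% and 29.3%, and the RFTSdel shares 74.9% and 71.1%.

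Across the 48783 regions of the merged lists, 1427 were called in all 5 DMSO libraries and in no DNMT1i library, and 75 showed the opposite. The DMSO lists were the longer ones in all 5 pairs, which favours the first count. The longest of the 1427 lay in ZBTB7A, a transcription factor gene of blood cell differentiation (chromosome 19, 4056775 to 4062974, 6200 bp). Next in length were regions near BRF1 on chromosome 14 (4329 bp) and DLL1 on chromosome 6 (4292 bp), a Notch ligand gene whose nearest end was 231960 bp away. Others covered PSD and FBXL15 on chromosome 10, MXI1, which encodes a MYC antagonist, SLC43A2, the cohesin gene STAG2 on chromosome X, SH3BP2 and MAD1L1, and 1 lay 7085 bp from SCAMP4. A further 103 regions were called in all 10 libraries. The best ranked of these lay at ERLIN1 and CHUK on chromosome 10 (100184847 to 100187241), at PHF19, KCNK9, AP4E1, RRP8 and ILK, SKIL, SMIM13, UBQLN4 and LAMTOR2, and ATAD3B, and at EEF1A1, which encodes a translation elongation factor (chromosome 6, 73518340 to 73521819). The count of 1427 depended on the threshold: it was 217 among peaks with −log10 q of at least 4, and it was 2153 without RFTSdel replicate 1 and 2856 without replicate 2.

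The strongest peaks called under 1 treatment only are given for each line. Whether these sites changed in the same way in the other lines was not tested. In NTC, 21393 DMSO peaks had no DNMT1i counterpart, led by peaks in DGKZ (chromosome 11, fold enrichment 9.45), SDK1, STAU2, CISD3 and EXTL3. The 3698 peaks called only after DNMT1i were led by CTTNBP2 (chromosome 7, fold 8.01), a site 103307 bp from RCN1, a long non-coding RNA locus on chromosome 4, HECW2 and PARD3B. In WT, 15449 peaks were called only under DMSO, led by HACL2, the pseudogene SLC7A5P2, PDXDC1, MED18 and GPD1L, and 3008 only after DNMT1i, led by JAKMIP3 (chromosome 10, fold 7.74), the potassium channel genes KCNG2 and KCNB2, DLGAP2 and DACT3. In UHRF1KO, the 29613 DMSO-only peaks were led by a peak over ATAD2 and NTAQ1, then FBXL12, CARM1, RABGAP1L and a tRNA gene on chromosome 13. The 1719 DNMT1i-only peaks were led by sites 3175 bp from ZFP37 and 411178 bp from UQCRFS1, a long non-coding RNA locus on chromosome 6, SAPCD2P2 and ZSCAN30. In RFTSdel, 2962 peaks were called in both DMSO and neither DNMT1i replicate, led by ZNF414, USP32, LRRC63, GINS4 and a site 8925 bp from SSC4D. Conversely, 900 were called in both DNMT1i and neither DMSO replicate, led by a long non-coding RNA locus on chromosome 9 (fold 11.8), HDGFL2 and sites near ZDHHC22, KCNIP1 and CALCA.

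Of the DNMT1i peaks, 36.7% (Wilson interval 35.5 to 38) overlapped a DMSO peak of the same line by at least 1 bp in NTC, 29.3% (27.9 to 30.7) in WT and 63.0% (61.6 to 64.3) in UHRF1KO. The RFTSdel share was 73.0% ± 2.73 (SD, n = 2). Random placement gave between 0.767% and 1.91%. The 2 RFTSdel pairs and the 2 wild-type pairs, NTC and WT, did not overlap (difference of means 40.0 points; exact permutation test, 2 against 2, p = 0.333, the smallest possible). This test was chosen after the values were seen. In the other direction, 9.23% of NTC, 8.98% of UHRF1KO and 7.54% of WT DMSO peaks were also called after DNMT1i, against 51.2% ± 7.21 (SD, n = 2) in RFTSdel. When every list was reduced to its strongest 4254 peaks, the first set of shares was 9.12% in NTC, 4.72% in WT, 26.9% in UHRF1KO and 58.1% in RFTSdel. The shares over the full lists were not particular to a line's own DMSO list. Against NTC DMSO (23568 peaks) they were 79.4% and 74.5% in RFTSdel, 66.5% in UHRF1KO and 30.4% in WT. Each was above the share with the own list. Against WT DMSO (16709 peaks) they were 73.9% and 67.6% in RFTSdel, 61.4% in UHRF1KO and 34.3% in NTC, each below it. The intervals cover counting error only.

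**Figure D2:**
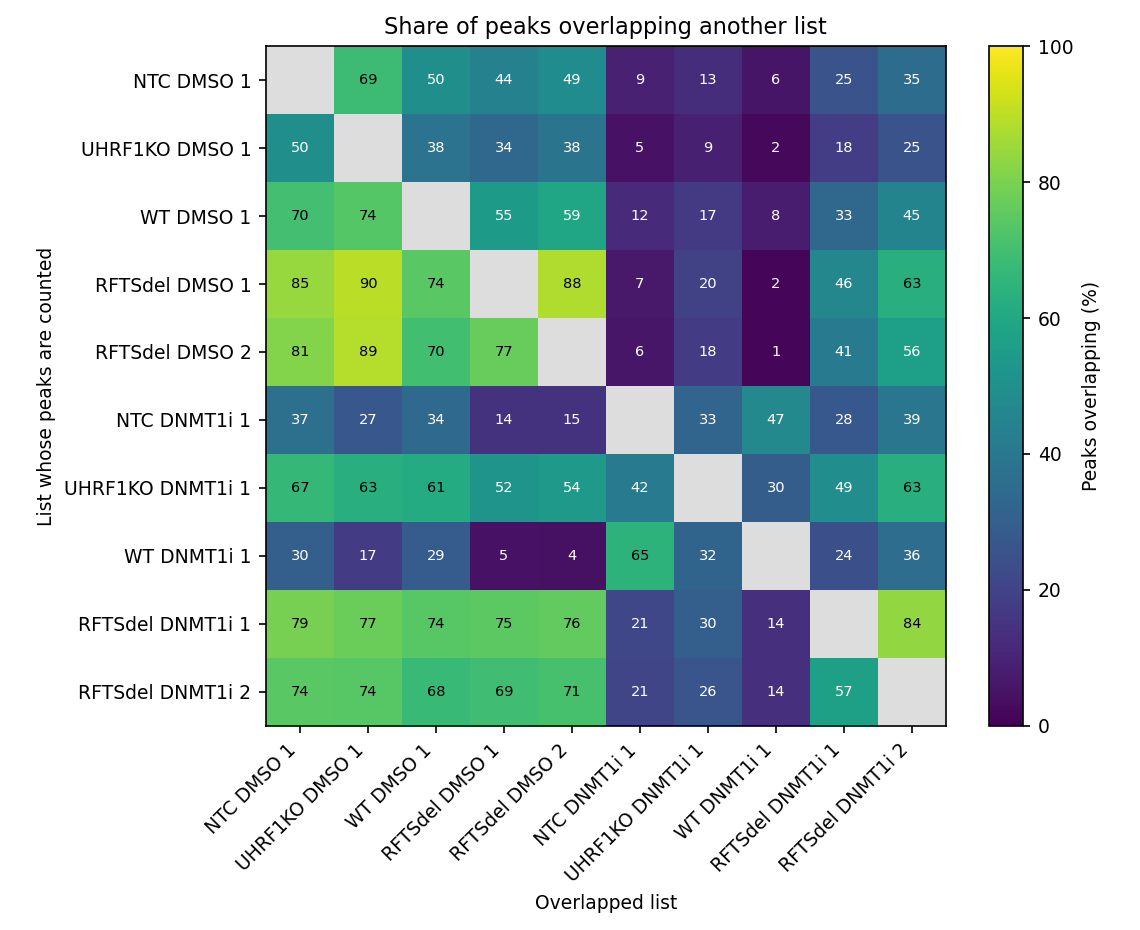
Each cell gives the percent of peaks in the row's list that overlap a peak of the column's list by at least 1 bp, for the 10 GFP-DNMT1 libraries after removal of parental peaks. RFTSdel DNMT1i peaks overlapped their DMSO lists by 74.9% and 71.1%, and WT DNMT1i peaks theirs by 29.3%. The RFTSdel DNMT1i peaks overlapped the NTC DMSO list by 79.4% and 74.5%, and the WT DMSO list by 73.9% and 67.6%.

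Peaks were concentrated at genes in every library. Under DMSO, the share within 1 kb of an end of a protein-coding gene was 39.5% in NTC, 30.9% in UHRF1KO, 47.6% in WT, and 63.7% and 59.0% in the RFTSdel replicates. Random placement gave 3.94% to 4.34%. After DNMT1i the shares were 45.9%, 58.7%, 44.5%, 67.8% and 65.3% in the same order. The mean change was 8.31 ± 11.5 points (SD, n = 5 pairs; exact sign-flip permutation p = 0.125), higher in every pair except WT. When each list was reduced to its strongest 4254 peaks the change was −7.79 points, lower in 5 of 5 pairs (exact sign-flip permutation p = 0.063). That cut kept all WT DNMT1i peaks and most of the NTC and UHRF1KO DNMT1i lists, but only the strongest part of each DMSO list. It did not even out peak strength, so the reversal cannot be credited to DNMT1i. The change was −0.81 points among peaks with −log10 q of at least 4. It was 3.45 points without the UHRF1KO pair. Within batch 1 the mean change was 2.46 ± 4.90 points (n = 3) and within batch 2 it was 17.1 ± 15.1 points (n = 2).

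Intergenic peaks were examined because the series concerns intergenic RNAs. Peaks outside every annotated gene made up 19.7% of the NTC, 22.7% of the UHRF1KO and 16.7% of the WT DMSO list, and 11.0% and 12.6% in RFTSdel, against 42.1% to 42.4% at random. After DNMT1i the shares were 15.0%, 13.0%, 15.6%, 9.28% and 10.4%. The mean change was −3.87 ± 3.54 points (SD, n = 5; lower in 5 of 5 pairs, exact sign-flip permutation p = 0.063), −1.66 ± 0.58 within batch 1 (n = 3) and −7.19 ± 3.59 within batch 2 (n = 2). It was −2.41 points without the UHRF1KO pair and 0.12 points at −log10 q of at least 4. With lists of equal length the change was 2.63 points, higher in 5 of 5 pairs (exact sign-flip permutation p = 0.063). Here too the cut did not even out peak strength, so this reversal cannot be credited to DNMT1i. Peaks in gaps of at least 100 kb between genes were rare, between 1.02% and 4.82% of a list against 22% to 22.8% at random, and their share differed between treatments by 0.37 ± 1.55 points (n = 5, exact permutation p = 0.6875).

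Among the gene lists, the DNA methylation and SUMO list and the ribosomal protein and housekeeping list had the highest shares of members with a peak at a gene end under DMSO. The ribosomal protein and housekeeping list had a peak at 74.4% of its 100 members on average under DMSO and at 21.4% after DNMT1i, with a difference of −53.0 ± 13.8 points (n = 5). ACTB, EEF1A1 and RPS2 had a peak in all 10 libraries. In WT the list went from 62 members to 3, and in NTC from 79 to 10. Replication-dependent histone genes, which supply the nucleosomes of S phase, had a peak at 58.0% and 10.7% of 69 members. None of them had 1 in WT DNMT1i, while H2BC12 was marked in 8 libraries and H1-4, H2AC11 and H2AC20 in 7. The DNA methylation and SUMO list went from 77.1% to 32.2% of 41 members, with CBX3, PCNA, SUMO2 and UHRF2 marked in every library except WT DNMT1i. For all 20037 protein-coding genes the means were 48.2% and 22.1%.

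The viral sensing and interferon list had a peak at 55.1% of 37 members under DMSO and 16.8% after DNMT1i. CMPK2 and its neighbour RSAD2, both interferon induced, were marked in 8 libraries, and the DNA sensor gene CGAS and IRF1 in 7. Of the 35 myeloid and leukaemia genes, 61.7% and 27.4% were marked. HOXA9 and HOXA10, homeobox genes expressed in many acute myeloid leukaemias, had a peak in all 10 libraries, and CEBPA and MYB in 9. Lymphoid and erythroid genes, which stand for other lineages, were marked at 18.0% and 6.0% of 30 members, with RAG1 in 7 libraries, KLF1 in 5 and BCL11B and EBF1 in 4. All 5 pairs were lower after DNMT1i for the housekeeping, histone, DNA methylation, viral sensing, myeloid and zinc finger lists (exact sign-flip permutation p = 0.063 each, adjusted over the 11 lists 0.115). The lymphoid and erythroid list was lower in 4 of 5 (p = 0.1875, exact permutation, adjusted 0.258). With lists of equal length the mean differences were −14.6 points for the DNA methylation and SUMO list, −8.80 for housekeeping genes, −5.41 for viral sensing, −1.14 for zinc finger genes and −0.87 for histones. Those of the myeloid list and of the lymphoid and erythroid list reversed, to 0.57 and 1.33 points. Lists of equal length are not of equal peak strength, which limits these differences.

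**Figure D3:**
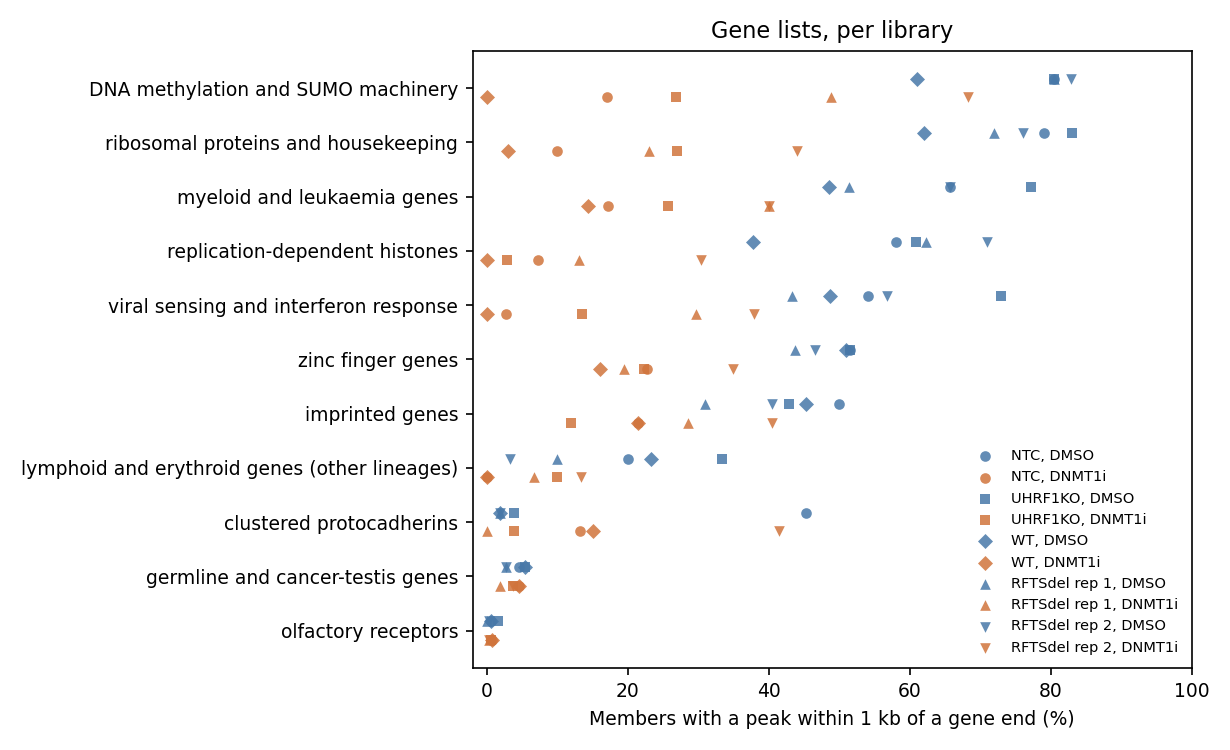
Percent of each gene list's members with a peak within 1 kb of a gene end, per library, with colour for treatment and marker shape for the pair. Housekeeping genes had a mean of 74.4% under DMSO and 21.4% after DNMT1i, and olfactory receptor genes lay near 0 under both.

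Germline and cancer-testis genes had a peak at 4.18% of 110 members under DMSO and 3.64% after DNMT1i (exact permutation p = 0.5, lower in 3 of 5 pairs, adjusted 0.611), against the means of 48.2% and 22.1% for all protein-coding genes. MOV10L1, a piRNA pathway gene, was marked in 9 libraries, DMRTB1 in 5 and MAEL in 4. SSX2IP, marked in 7, is in the list by its symbol and is not itself a cancer-testis antigen gene. Olfactory receptors had 0.561% and 0.510% of 392 members (exact permutation p = 1, adjusted 1), the most often marked being OR2L13 in 6 libraries, OR52K1 in 3, and OR1R1, OR2AE1, OR3A2 and OR52N2 in 2. Imprinted genes had 41.9% and 24.8% of 42 members (lower in 4 of 5 pairs, exact permutation p = 0.125, adjusted 0.196), with UBE3A in 9 libraries, CDKN1C and RB1 in 8 and GRB10 in 7. With lists of equal length the mean difference of the imprinted list reversed from −17.1 to 4.29 points. Clustered protocadherins had 10.9% and 14.7% of 53 members, with opposite differences between pairs (exact permutation p = 0.75, adjusted 0.825). They were marked at 24 members in NTC DMSO and 7 in NTC DNMT1i, and at 1 and 22 in the RFTSdel replicate 2 pair. These counts are not independent: 22 members share 1 annotated gene end, and a single peak there marked all 22 in NTC DMSO and in RFTSdel DNMT1i replicate 2. PCDHGC3 was marked in 5 libraries and PCDHAC1, PCDHAC2 and PCDHGA5 in 3.

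Zinc finger genes, many of which encode repressors of transposable elements, had a peak at 48.9% of 528 members under DMSO and 23.1% after DNMT1i. ZNF32, ZNF354A, ZNF75A and ZNF775 were marked in all 10 libraries. Under DMSO, 272 members were marked in NTC, 272 in UHRF1KO, 269 in WT, and 231 and 246 in RFTSdel, against means of 284, 304, 246, 255 and 271 in 10000 random lists of protein-coding genes matched for gene length. After DNMT1i, 120 members were marked in NTC, 118 in UHRF1KO and 85 in WT, against means of 69.5, 83.6 and 44.6 in random lists. In the RFTSdel DNMT1i replicates 103 and 184 members were marked, against 155 and 224 in random lists. The strongest DMSO peaks, as many as the DNMT1i list holds, marked 131 members in NTC, 99 in UHRF1KO, 86 in WT, and 149 and 206 in RFTSdel, so the counts in NTC and WT were about as high without DNMT1i. These counts describe single libraries and are no test between constructs.

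The gene encoding DNMT1 itself had a peak at its end (chromosome 19, gene at 10133346 to 10194953) in all 5 DMSO libraries. After DNMT1i it was called in both RFTSdel replicates and UHRF1KO and was not called in NTC or WT. UHRF1 (chromosome 19, 4903080 to 4962154) had peaks inside the gene in all 5 DMSO libraries and in both RFTSdel DNMT1i replicates, with none called in the other 3 DNMT1i libraries. The parental list had no peak in either gene.

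The requirement for UHRF1 was addressed by UHRF1KO against NTC, 1 library each. Under DMSO the UHRF1KO list was longer, with 32534 peaks against 23568 (log2 ratio 0.47), and under DNMT1i it was shorter, with 4642 against 5844 (log2 ratio −0.33). Under DMSO 49.6% of UHRF1KO peaks overlapped NTC peaks (Wilson interval 49.1 to 50.2, random placement 1.52%), and 68.5% of NTC peaks overlapped UHRF1KO peaks (68.0 to 69.1). Under DNMT1i the shares were 41.7% (40.3 to 43.1) and 32.8% (31.6 to 34.0). With lists of equal length they were 59.3% and 59.5% under DMSO and 37.7% and 37.4% under DNMT1i (near equal in both directions by construction), and at −log10 q of at least 4 they were 31.2% and 60.2%, and 24.0% and 18.7%. The strongest DMSO peaks without an NTC counterpart lay near MIF and in UBE3D, IPO8, MICALL1 and GCC1, and those only in NTC in TXNIP, G2E3, RHOV, HES7 and TRAPPC9. Under DNMT1i the peaks called only in UHRF1KO were led by JOSD2 (chromosome 19, 50511112 to 50511477, fold 7.29), CISD3, COA3 and CNTD1, STAU2 and a long non-coding RNA locus. CISD3 and STAU2 were also among the strongest NTC peaks called only under DMSO. The peaks called only in NTC lay 103307 bp from RCN1, at a long non-coding RNA locus, and in AUTS2, IQANK1 and GLT1D1. The log2 ratio of DNMT1i to DMSO was lower in UHRF1KO than in NTC by a difference of −0.80, which was not tested. At −log10 q of at least 4 the DMSO ratio was 0.95 and this difference −1.31.

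The contribution of the RFTS domain was addressed by RFTSdel against WT. Under DMSO the RFTSdel lists were shorter than the WT list (mean log2 ratio −0.35 ± 0.14, SD, n = 2 RFTSdel libraries against 1), and under DNMT1i they were longer (1.11 ± 0.40, n = 2). The latter rests on WT DNMT1i, which called 24.2% of the regions that the other 9 libraries all called. Against NTC in place of WT the means were −0.85 under DMSO and 0.65 under DNMT1i. The DMSO direction depended on the threshold: the mean log2 ratio was 0.22 at −log10 q of at least 2, 1.93 at 4 and 0.50 at a fold enrichment of at least 4. The DNMT1i ratio was 2.07 at −log10 q of at least 4. Under DMSO 72.1% of RFTSdel peaks overlapped WT peaks on average and 56.6% of WT peaks overlapped RFTSdel peaks. Under DNMT1i these means were 13.7% and 30.1%. With lists of equal length the shares were 64.1% and 63.9% under DMSO and 8.25% and 8.32% under DNMT1i, where the 2 directions are near equal by construction. The DMSO shares were 57.2% and 66.5% at −log10 q of at least 2, 20.3% and 77.1% at 4, and 43.9% and 62.0% at a fold enrichment of at least 4. The DNMT1i shares were 6.95% and 18.3%, 0.88% and 3.86%, and 9.01% and 15.7% in that order. RFTSdel replicates overlapped each other at 88.2% of replicate 1 and 76.7% of replicate 2 peaks under DMSO, and at 84.0% and 56.7% under DNMT1i. The difference in the DNMT1i effect, RFTSdel minus WT, was 1.46 on the log2 scale, and 0.14 at −log10 q of at least 4. It was not tested.

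Several of the strongest RFTSdel peaks were absent from WT under both treatments. A peak in DNAH8, an axonemal dynein gene (chromosome 6, from 39029078), had a fold enrichment of 21.6 under DMSO and 19.6 under DNMT1i in replicate 1. A site 18982 bp from the defensin gene DEFA1 on chromosome 8 had 11.2 and 16.1, and a peak in OXTR, the oxytocin receptor gene on chromosome 3, had 13.6 and 16.2. Unlike those at DNAH8 and near DEFA1, the merged region at OXTR was also called in at least 1 library of NTC, UHRF1KO or WT, which carry wild-type DNMT1. A site near PPP2R2D and a peak in SEZ6L completed the first 5 under DMSO, and peaks in GRAMD1A and ZBTB46 those under DNMT1i. The strongest peaks called only in WT under DMSO lay 171919 bp from SMOC2, near SLC6A13, and in SCARF1, EPS15L1 and MAPK15. Those under DNMT1i lay at the same site near SMOC2 and in JAKMIP3, KCNG2, DLGAP2 and ZSCAN1.

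Regions common to both wild-type pairs were then examined. NTC and WT shared 10004 regions called under DMSO and not under DNMT1i, and 1235 called under DNMT1i and not under DMSO. Independent lists would share 334 of the latter, a ratio of 3.69. Of the 10004 regions, 75.1% and 80.1% were called in the RFTSdel DMSO replicates and 42.4% and 57.1% in their DNMT1i counterparts, and 92.0% were called in UHRF1KO DMSO and 16.8% in UHRF1KO DNMT1i. Merged regions of this class lay within 1 kb of an end of DNMT3B, TET1, FLT3, KIT, MYC, ELANE and PRTN3. They also did so at 48 of the 100 housekeeping genes, against 33.6% of all protein-coding genes. A region can be lost only where it was called under DMSO, and housekeeping genes were marked more often there. Under DMSO, 62 of the 100 were marked in WT and 79 in NTC, against 44.2% and 50.8% of all protein-coding genes. The higher count therefore does not show preferential loss at these genes. A merged region can reach a gene end through a peak of another library, so NTC or WT need not have a peak at that end. Of the 1235 regions, 0.648% and 0.567% were called in the RFTSdel DMSO replicates, 19.6% and 32.1% in their DNMT1i counterparts, 8.10% in UHRF1KO DMSO and 34.6% in UHRF1KO DNMT1i. Over all 48783 regions the shares were 24.7% and 28.4% in the RFTSdel DMSO replicates and 15.3% and 22.5% in their DNMT1i counterparts. They were 65.9% in UHRF1KO DMSO and 9.39% in UHRF1KO DNMT1i. All regions are no matched baseline, because the classes are defined by the NTC and WT lists and the DMSO lists overlap. Of RFTSdel DMSO peaks, 84.6% and 81.4% overlapped NTC DMSO, so the DMSO shares follow in part from the definition. The 675 regions called in NTC and WT under both treatments had 26.1% and 28.9% in RFTSdel DMSO and 55.4% and 71.1% in RFTSdel DNMT1i. These region classes were defined after the lists had been compared. They rest in part on WT DNMT1i, which called 24.2% of the regions that the other 9 libraries all called.

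**Figure D4:**
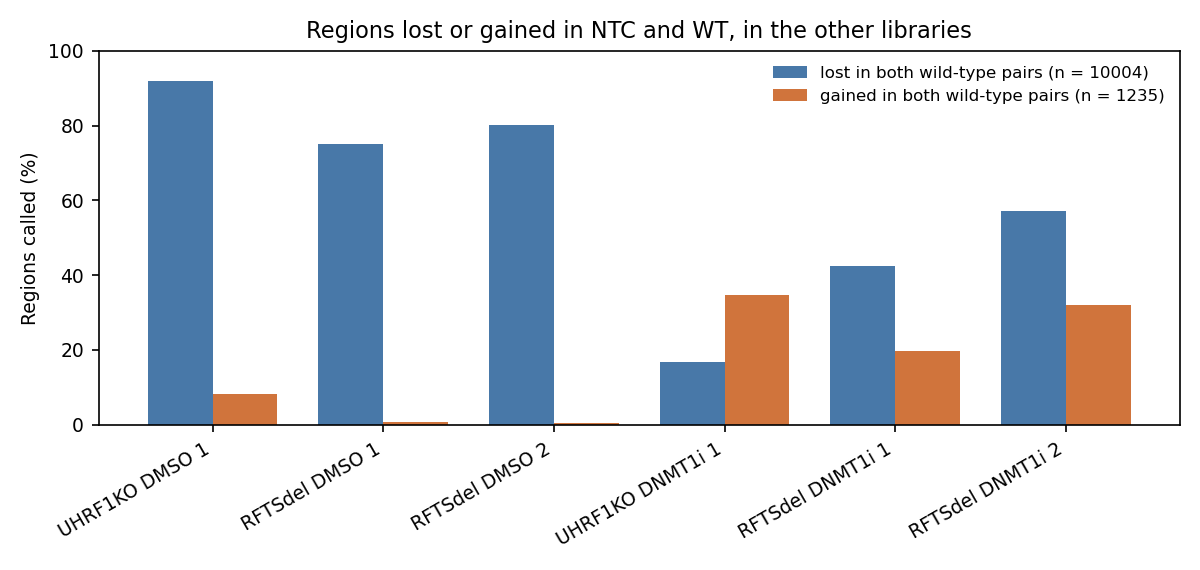
Percent of regions called in the UHRF1KO and RFTSdel libraries, for the 10004 regions called under DMSO only and the 1235 called under DNMT1i only in both NTC and WT. The first class was called at 75.1% and 80.1% in the RFTSdel DMSO replicates and at 42.4% and 57.1% in the RFTSdel DNMT1i replicates.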

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

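The tests of shared gained regions, of list length for the parental peaks and of the part of the housekeeping difference that goes with list length were chosen after the results were seen. The UHRF1KO list was longer than the NTC list under DMSO (log2 ratio 0.47) and shorter under DNMT1i (−0.33), and the difference was not tested. The RFTSdel lists were shorter than WT under DMSO (mean log2 ratio −0.35) and longer under DNMT1i (1.11), in both replicates, again without a test, but the DMSO direction reversed at −log10 q of at least 2 (0.22) and 4 (1.93) and at a fold enrichment of at least 4 (0.50). The share of peaks near gene ends was lower after DNMT1i in WT (−3.06 points) and higher in both RFTSdel pairs (4.14 and 6.31 points), which was not tested. In the mitochondrial genome, which the comparisons left out, 1 peak was called in RFTSdel DNMT1i replicate 1 and 1 in WT DNMT1i, from positions 16041 and 16031, with fold enrichments of 1.40 and 1.49, and none in parental cells.

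DNMT1i peaks of the wild-type constructs (NTC and WT) lay mostly outside their DMSO lists, and those of RFTSdel mostly inside. Restricting DNMT1i peaks to −log10 q of at least 4 left a gap of 44.7 points (NTC 50.3%, WT 46.8%, RFTSdel 92.7% and 93.7%), which argues against peaks near the calling threshold as the whole cause. Lists of equal length left 51.2 points, which argues against list length as the whole cause. That cut kept all 4254 WT DNMT1i peaks but only the strongest of the 7561 and 11141 RFTSdel DNMT1i peaks. It therefore did not even out peak strength. Random calls are also argued against, since WT and NTC, from different batches by their labels, shared 3.69 times as many gained regions as independent lists would. UHRF1KO, with wild-type DNMT1, had 91.0% at the stricter threshold, on the side of RFTSdel, and 26.9% with lists of equal length, between the groups. Construct, UHRF1 status, depth and the level of the GFP proteins were not tested as causes and all remain open, with 1 or 2 libraries per group.

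Ribosomal and housekeeping genes had few peaks after DNMT1i in the wild-type constructs. Cutting the DMSO list to its strongest peaks, as many as the DNMT1i list holds, took the members marked from 62 to 18 in WT and from 79 to 27 in NTC, so 74.6% and 75.4% of the difference go with list length. The remainder was 18 against 3 in WT, a difference of 15, and 27 against 10 in NTC, so under this cut list length did not account for all of it. The cut set only the strongest DMSO peaks against every DNMT1i peak. It did not even out peak strength, so the remainder cannot be credited to DNMT1i. The Wilson intervals of the shares did not overlap, but they cover counting error only, with 1 library per treatment and the same genes in both lists. The remaining difference was 3 in UHRF1KO and 19 and 22 in RFTSdel, so it was not specific to the wild-type constructs. Antibody signal at active genes in the DMSO libraries could contribute and cannot be told apart from DNMT1 binding here, because the parental list is short and marked only 3 of the 100 genes.

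WT DNMT1i called 16% of the parental peaks. UHRF1KO DNMT1i, with a list of similar length, called 94.6%, which argues against list length. Of the regions outside the parental list that the other 9 libraries all called (by coincidence also 426), WT DNMT1i called 24.2%, which is consistent with weak enrichment at strong sites in general in that library. The same share was 80.5% of 128 regions for NTC DNMT1i and 79.2% of 130 for UHRF1KO DNMT1i. These are different sets of regions, which WT DNMT1i itself had to call. The median fold of the called peaks was 4.18 in WT DNMT1i and 4.10 in UHRF1KO DNMT1i, while the highest deposited fold was 15.8 against 34.7. The median cannot show whether enrichment was weak, because only peaks that passed the cutoff enter it. NTC DMSO, which called 99.3% of the parental peaks, had a lower median fold of 3.77. No biological explanation was tested, and comparisons that rest on WT DNMT1i carry this limit.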

How the results depend on the processing

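Leaving out the NTC, UHRF1KO or WT pair, and all alternatives for the overlap of DNMT1i with DMSO peaks, were chosen after seeing the data. Peak number and covered length stayed lower after DNMT1i under every alternative run (mean log2 ratios from −2.43 to −1.25 and from −2.62 to −1.21). No test could pass 0.05 under any setting, so p-values say nothing about stability here. Of 245 recomputed values, 141 were counted as kept, 89 as moved and 15 as reversed. For results with a permutation test only the direction decided, so the count of kept values overstates stability. The histone list was counted as kept although its difference went from −47.2 to −0.87 points with lists of equal length. Other values had to stay within their spread, or within a set factor for counts. The cause was not tested unless stated, and unknown depth limits every comparison of list length.

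At −log10 q of at least 2, regions lost in all 5 pairs numbered 925, the UHRF1KO to NTC log2 ratio was 0.64 under DMSO and −0.56 under DNMT1i (difference −1.20), RFTSdel to WT under DMSO reversed to 0.22 with a DNMT1i effect difference of 1.13, and the overlap shares were 19.3% (NTC), 17.1% (WT), 60.9% (UHRF1KO) and 81.2% (RFTSdel). At −log10 q of at least 4, the lost regions numbered 217, UHRF1KO to NTC under DMSO was 0.95 (difference −1.31), RFTSdel to WT was 1.93 under DMSO, reversed, and 2.07 under DNMT1i (difference 0.14), the changes in gene-end and intergenic share reversed to −0.81 and 0.12 points, and the overlap shares were 14.9% (NTC), 1.74% (WT) and 84.8% (RFTSdel). At a fold enrichment of at least 4, the values were 842 regions, 0.56 and −0.26 for UHRF1KO to NTC, 0.50, reversed, for RFTSdel to WT under DMSO (effect difference 0.30), and shares of 14.0% (NTC), 12.6% (WT) and 44.2% (UHRF1KO).

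With peaks merged within 5 kb, UHRF1KO to NTC was 0.39 under DMSO (difference −0.69) and the shares were 38.3% (NTC) and 64.6% (UHRF1KO). With parental peaks kept these shares were 40.3% and 66.0%. With 50% of a peak covered they were 24.5% (NTC), 18.6% (WT), 55.1% (UHRF1KO) and 66.5% (RFTSdel). With lists of equal length they were 9.12%, 4.72%, 26.9% and 58.1% in that order, the gene-end and intergenic changes reversed to −7.79 and 2.63 points, and the germline (1.27 points), imprinted (4.29), myeloid (0.57), lymphoid and erythroid (1.33) and olfactory (0.36) lists reversed. The cut to equal length did not even out peak strength between treatments. Over gene bodies the germline (1.27), protocadherin (−10.6) and olfactory (0.051) lists reversed. Against NTC as comparator, RFTSdel had log2 ratios of −0.85 under DMSO and 0.65 under DNMT1i. Leaving out 1 pair at a time gave 1620 to 2856 regions lost in the remaining 4 pairs, more by construction since fewer libraries must agree.

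The RFTSdel replicates share only a number: over 19204 regions the deviations of same-numbered DMSO and DNMT1i libraries had a correlation of −0.045 across regions. With the replicate block, 51.2% of RFTSdel DMSO peaks were retained after DNMT1i, against 51.6% over all 4 pairings. With no replicate block, the mean log2 ratio of peak number over 4 pairs was −1.83. The planned comparison of GC and CpG content was not run, since no sequence was used.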

Other observations

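The test of developmental genes and the swaps of treatment labels were chosen after the results were seen. Genes of developmental transcription factors were over-represented among the 1235 regions gained after DNMT1i in both NTC and WT, although most genes with such a region were others (39 of 652 protein-coding genes were in the list below). The longest regions included some at POU4F2 on chromosome 4 (146637269 to 146640763), FOXA2 on chromosome 20, FEZF1 on chromosome 7 and OTX1 on chromosome 2. A list of 266 genes of developmental transcription factor families was then drawn up. Of these, 39 had a gained region within 1 kb of an end, among them SOX1, SOX2, OTX2, NKX2-2, SALL1, NEUROG1 and HOXD12, against a mean of 7.65 in random lists matched for gene length. Without the 40 longest regions, from which the list was conceived, the number was 32, a ratio of 4.47. Of the 266 genes, 45 had a region lost in both wild-type pairs, against 82.1 in random lists. A region can be lost only where DMSO called it and gained only where DMSO did not. How often these genes were marked under DMSO was not examined. Neither count is therefore separated from their marking under DMSO.

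Developmental genes were also over-represented among regions gained in UHRF1KO (38 genes, ratio 4.60) and in both RFTSdel pairs (30 genes, ratio 4.26), each without its 40 longest regions, so the pattern was not particular to the wild-type constructs. CpG content and expression were not tested as causes of the ratios, since no sequence was used and the lists hold no expression values.

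Among the regions of the merged lists, 39 were called in all 4 RFTSdel libraries and in no other. The strongest lay in DNAH8, with fold enrichments from 15.5 to 21.6, on chromosome 8 at 6957801 to 6960211, with 11.2 to 17.8, and in SEZ6L, with 9.85 to 15.3. They were chosen after their values were seen.

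Among the 16 distinct swaps of DMSO and DNMT1i within the 5 pairs, 1 (the real assignment) gave 1427 regions called in all libraries of one side and none of the other, and the highest of the others gave 21. With 16 swaps no share under 0.05 can be reached. The DMSO list was the longer one in all 5 pairs, so any swap lowers this count by list length alone. The contrast of 1427 with 21 therefore adds no evidence beyond the peak numbers.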
